A study of Homo sapiens with 12 samples.

How the data were processed

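RNA from IMR32 cells was hybridised to 12 one-colour Agilent arrays, 3 for each of 4 treatments: 0.1% DMSO, 1 µM EPZ-6438, 1 µM 5-aza-dC and both drugs, taken 4 days after treatment. The labels do not say whether the replicates are separate cultures. Per the file headers, the intensity values were extracted with Agilent Feature Extraction 12.0.3.1, each array by itself, while the submitters' processing notes name version 11.5.1.1. The column used is the processed green signal, a linear intensity that was background-corrected by the scanner software per the file headers. The deposited value table was equal to this intensity column on every array, so that it carries no normalization between arrays.

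The arrays held 58717 gene spots and 4259 control spots. Control spots and 3801 outlier spot values were left out, and the spots of a probe were averaged. The files give no gene names, only accessions, which were matched without versions to the RefSeq gene table of GRCh38.p14. Of 50599 probes, 33346 matched 23849 symbols, 17253 kept the name in the files, and 579 NM or NR accessions had no match. The array annotation is hg19 per the file headers, so no coordinates are given. Log2 of the processed signal minus each array's 75th percentile was the working value. Probes were kept if well above background on all 3 arrays of at least 1 group, and a gene was represented by its kept probe with the highest mean, which left 20707 genes, 16221 of them with a symbol. Of 4347 genes with several kept probes, between 7 and 182 had probes called in opposite directions, depending on the comparison. Among named genes these were MBD2 (5-aza-dC and both drugs against DMSO), CASC15 and LCOR (both drugs against DMSO) and GRB10 (both drugs against EPZ-6438).

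All 12 arrays were fitted together with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with data.table (1.17.8) and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The contrasts numbered 6: each drug and both drugs against DMSO, both drugs against each single drug, and the interaction, which is the effect of EPZ-6438 with 5-aza-dC minus its effect without. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast. A gene was called changed at an adjusted p under 0.05, and rose, fell, higher and lower refer to such calls. Values after ± are standard errors of the fit, or SDs where stated. Where a gene was not well above background on any array of the dimmer group, the fold is a lower bound, written "at least". It sets the brighter group's mean against the mean of, per array, the higher of the lowest signal well above background and the probe's own. No fold is given where both groups were below background.

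The 26 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists within a contrast. Estimated correlations and fry, which tests whether a list's genes move one way on balance, were alternatives. Calls that held with the estimated correlation numbered 6 of 8 for EPZ-6438 and 4 of 13 for 5-aza-dC against DMSO, 12 of 16 for both drugs against DMSO, 6 of 13 for both drugs against 5-aza-dC, 7 of 13 for both drugs against EPZ-6438 and 2 of 6 for the interaction. Counts adjusted over the list alone are given for the called lists in which they differ. Named genes were chosen by a rule also fixed before: per contrast, the 6 highest and 6 lowest fold changes among called genes with a symbol, non-overlapping groups and a higher group well above background on all 3 arrays; up to 3 members with the smallest p of each list; and EZH2, DNMT1, MYCN, CASZ1, CLU, RUNX3, NGFR, CDKN1A and CASP8. Y-linked genes that met the rule are left unnamed, and a few other named genes are not reported here.

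The procedure was tested on data simulated from the real means and spreads. For EPZ-6438 against DMSO, run on 20701 genes, it recovered 62.7% of 67, 77.6% of 67 and 95.5% of 66 genes changed by a log2 value of 0.5, 1 and 2, with 6 calls among unchanged genes. For the interaction it recovered 16.4%, 64.2% and 89.4% of as many genes, with 9 such calls. Of 20 simulated lists, the 1 shifted list was called and 0 others. The simulated noise was independent between genes, so this does not test list calls among correlated genes. Few genes were changed in the simulation, so its recovery need not hold for contrasts with wide changes. Replicates 1 and 2 of each group lay on slide 1 and replicate 3 on slide 2, so slide was not confounded with treatment.

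Alternatives set before the data were examined were quantile normalization, median scaling, no filter or a filter on all 12 arrays, the mean over a gene's probes, outlier spots kept, an intensity trend, array quality weights, the slide or the replicate number as a block, the deposited value table, only the arrays compared, and each array left out in turn. Chosen after seeing the data were scaling to the 8 spike-in probes, values raised to the lowest signal well above background, and slide 1 alone. Leaving out 3 arrays whose headers gave the median variation of gene spots as out of range was chosen then too. Headers also flagged other measures. Variation of spike-in spots was out of range on replicates 1 and 3 of DMSO and EPZ-6438. It was so too on replicates 1 and 2 of 5-aza-dC and replicate 1 of both drugs, which limits the spike-in scaling. The net signal of negative controls was out of range on every array, and the detection limit on most. Normexp was planned on mean signals, which the files lack, and was run on median signals with an offset of 50.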

Results

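Gene expression was measured on 12 one-colour Agilent arrays in IMR32, an established human neuroblastoma cell line with amplified MYCN. Cells received vehicle (0.1% DMSO), 1 µM EPZ-6438 (tazemetostat, an inhibitor of the histone methyltransferase EZH2), 1 µM 5-aza-dC (decitabine, an inhibitor of DNA methyltransferases), or both drugs, with 3 arrays per group. RNA was taken 4 days after treatment. The series title names resistance to EZH2 inhibition and genome methylation, so the comparisons ask what each drug changed alone, what EPZ-6438 changed on top of 5-aza-dC, and whether its effect differed between the 2 settings. The mean share of gene spots well above background was 50.5% ± 0.587 (SD, n = 3) in DMSO and 50.7% ± 0.0874 with EPZ-6438. It was 54.9% ± 2.0 with 5-aza-dC and 57.9% ± 2.48 with both drugs. The 6 arrays with 5-aza-dC lay at 56.4% ± 2.59 and the 6 without at 50.6% ± 0.387, a difference with p = 0.00216 (exact permutation test, two-sided, 924 splits). No spot was saturated, and the number of arrays limits the precision.

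The first principal component of the 20707 tested genes held 78.4% of the variance and separated arrays with and without 5-aza-dC. The second held 6.78% and separated arrays with and without EPZ-6438. Pearson's r across genes was 0.988 or higher between arrays of 1 group, and genes are not independent replicates. How arrays are scaled decides how many genes count as higher or lower after 5-aza-dC. With each array scaled to its median, the median log2 change of all genes was -0.49 for 5-aza-dC, -0.70 for both drugs against DMSO and -0.70 for both drugs against EPZ-6438, where scaling to the 75th percentile gave -0.0553, -0.0612 and -0.0161. Scaling to the spike-in probes gave 0.20, 0.24 and 0.37 for the same comparisons, and -0.11 for EPZ-6438 against DMSO. For both drugs against 5-aza-dC the median scaling gave -0.22, and for the interaction the median and spike-in scalings gave -0.24 and 0.15. For both drugs against DMSO, normexp correction gave -0.13. Gene list tests below compare each list with all other genes, so that they are relative to this shift.

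**Figure D1:**
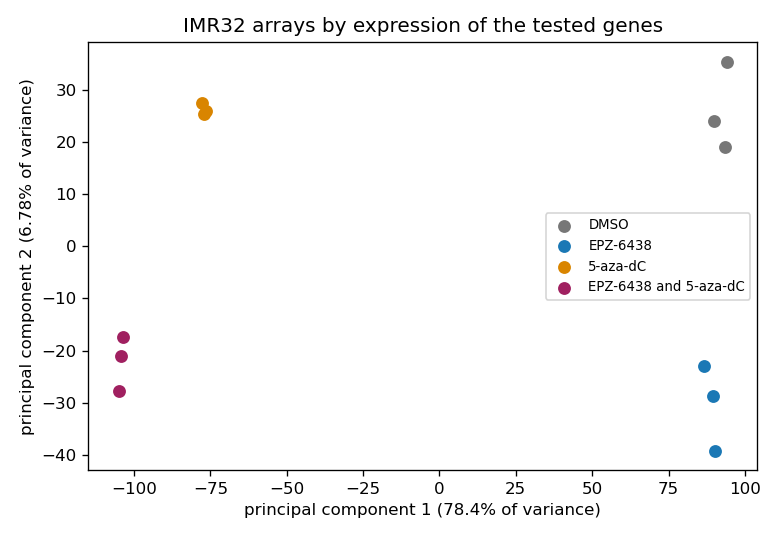
The 12 arrays on the first 2 principal components of the tested genes, with the share of variance on each axis label and 3 points per treatment. Arrays with 5-aza-dC lie at negative values of the first component, which holds 78.4% of the variance, and arrays with EPZ-6438 at negative values of the second, which holds 6.78%.

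EPZ-6438 alone raised 19 of 44 genes of neuronal differentiation, 19 of 70 developmental transcription factors and 7 of 20 genes of MHC class I antigen presentation. Several of the genes that rose were not well above background in DMSO. HLA-DPB1, an MHC class II chain, was at least 18.8-fold higher (adjusted p = 1.52e-10), and the X-linked BEX5 at least 16.0-fold higher (adjusted p = 8.33e-08). CADM3, a neuronal adhesion molecule, was at least 15.0-fold higher. The junctional adhesion molecule F11R, HEPACAM2 and the monocyte chemokine CCL2 were at least 9.73-fold, 6.70-fold and 6.06-fold higher. Among decreases, the neuronal transmembrane gene SLITRK6 fell by 2.14 ± 0.157 on the log2 scale (SE, n = 3 per group, adjusted p = 1.52e-05). The hedgehog-pathway transcription factor GLI1 fell by 1.76 ± 0.174 and the interferon-stimulated IFI44L by 1.49 ± 0.105. MYBPC2 fell by 1.37, PTPN14 fell by 1.12, and TCL1B was at least 1.87-fold lower.

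In the MHC class I antigen presentation list, 7 of 20 tested genes rose and 0 fell after EPZ-6438 (camera adjusted p = 0.00261). HLA-B rose by 4.01 ± 0.247 on the log2 scale, from DMSO signals well above background on 2 of 3 arrays, HLA-C by 3.32 ± 0.197 and the peptide transporter TAP2 by 2.01 ± 0.109. The list's median was only 0.05 and turned to -0.03 with spike-in scaling, while its mean was 0.62. Of 5 genes reported before as silenced by EZH2 in neuroblastoma, 4 rose (adjusted p = 0.000284), and 5 did when adjusted over the list alone. The nerve growth factor receptor NGFR rose by 0.87 ± 0.116 and the transcription factor CASZ1 by 0.40 ± 0.0572. CASZ1 was not called when its probes were averaged or on slide 1 alone. RUNX3 was well above background on 2 of 3 arrays with EPZ-6438 and on 0 with DMSO. CLU changed by 0.22 (adjusted p = 0.143).

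Among neuronal differentiation genes, 19 of 44 rose and 0 fell (adjusted p = 1.86e-07). The intermediate filament gene PRPH rose by 0.71 ± 0.0468, STMN4 by 1.75 ± 0.126 and DPYSL3 by 0.47 ± 0.0629. Of 21 HOX genes 6 rose and 0 fell (adjusted p = 0.00213), with HOXC13 at 1.46 ± 0.159 and HOXD13 at 1.28 ± 0.151. Of 70 developmental transcription factors that are classic targets of the Polycomb complex, 19 rose and 2 fell (adjusted p = 0.000988). That list's median was 0.08, and -0.01 with spike-in scaling. LHX1 rose by 1.29 ± 0.0502, SIX6 by 1.52 ± 0.0681 and MSX1 by 0.97 ± 0.0551. In the cholesterol biosynthesis list 7 of 25 genes rose and 0 fell (adjusted p = 0.000465), with MVK, STARD4 and IDI1 at 0.34, 0.63 and 0.33. Of 17 NF-kB and inflammatory genes 6 rose, among them TNFAIP3 and BCL3 (adjusted p = 0.000988, and 0.0521 with an estimated correlation). Of 9 Schwann cell markers 5 rose, including POU3F1, GFRA3 and PMP22 (adjusted p = 0.00966, and 0.191 with an estimated correlation). The NF-kB and Schwann cell lists were not called after normexp correction, and the NF-kB list not with only probes well above background on all arrays. Adjusted over the list alone, 24 neuronal genes, 20 developmental transcription factors and 9 cholesterol genes rose.

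The drug target's own mRNA did not pass the test after EPZ-6438: EZH2 changed by -0.00388 ± 0.154 (adjusted p = 0.99) and DNMT1 by -0.04 ± 0.0577 (adjusted p = 0.66). MYCN was lower by a log2 change of -0.19 ± 0.0526 (adjusted p = 0.0404), a call lost on slide 1 alone, with quantile normalization (-0.08), with median scaling (-0.15) and without any 1 of the DMSO arrays. The cell cycle list was not called, with 2 of 66 genes higher and 1 lower (adjusted p = 0.703). Counts of higher and lower genes in the other lists not called were 1 and 1 of 13 PRC2 subunits, 1 and 0 of 16 DNA methylation genes, and 7 and 4 of 82 cancer-testis genes. They were 5 and 4 of 33 interferon-stimulated genes, 1 and 0 of 4 interferons and endogenous retroviral genes, 5 and 2 of 34 p53 targets, and 7 and 3 of 37 apoptosis regulators. For cell states they were 4 and 5 of 30 adrenergic genes, 7 and 3 of 36 mesenchymal genes, 4 and 2 of 13 fibroblast markers, 3 and 0 of 15 epithelial markers, and 1 and 0 of 13 blood and endothelial markers. The remainder were 5 and 3 of 30 imprinted genes, 2 and 2 of 34 protocadherins, 6 and 2 of 29 tumour suppressor genes, 0 and 1 of 40 MYCN targets, and 5 and 3 of 30 stress response genes. Of the 4 lower cancer-testis genes, 0 had their higher group well above background on all 3 arrays. The same held for the 2 lower protocadherins and the 1 higher blood and endothelial marker. With slide as a block, camera called the p53 targets as higher (adjusted p = 0.048) and the MYCN targets as lower (adjusted p = 0.0492).

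In all, 2716 of 20707 genes differed between EPZ-6438 and DMSO, 1733 higher and 983 lower, and 520 did so by at least 2-fold, 448 of them higher. Of those 520, 399 had their higher group well above background on all 3 arrays, 370 of the 448 higher genes and 29 of the 72 lower ones. The groups did not overlap for 32.9% of genes, against 10% by chance. Of the changed genes 63.8% were higher, but 78% with median scaling and 35.3% with spike-in scaling. The count was 1496 with only the 6 arrays of this comparison and 1053 on slide 1 alone. At least 2-fold changes numbered only 86 with normexp and 200 with only probes well above background on all arrays. With values raised to the lowest signal well above background they numbered 321.

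5-aza-dC alone raised germline genes and protocadherins and lowered MYCN target and cholesterol genes. Cell cycle genes were lower too, by a call lost with an estimated correlation (adjusted p = 0.0523). RHOXF2, a reproductive homeobox gene, was at least 1707-fold higher than in DMSO (adjusted p = 2.91e-11). The transketolase-like TKTL1 was at least 2601-fold higher and the cancer-testis antigen CTAG1A at least 941-fold higher. DMRTB1 and MAGEA2B were at least 410-fold and 507-fold higher. In the cancer-testis and germline list 68 of 82 genes rose and 7 fell (adjusted p = 1.15e-23), with a median log2 change of 5.42, or 3.82 with genes at their bound. MAEL, LUZP4 and PASD1 in this list were at least 206-fold, 46.5-fold and 85.7-fold higher. All but 3 of the 34 clustered protocadherins rose, which is 31 genes with 0 lower (adjusted p = 4.67e-12). PCDHB2 rose by 2.53 ± 0.0677 on the log2 scale and PCDHGA8 by 1.81 ± 0.0765.

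Among genes lower after 5-aza-dC, the non-coding RNA OLMALINC fell by 3.08 ± 0.23 on the log2 scale and the growth factor VEGFD fell by 2.83 ± 0.0766. The telomerase gene TERT fell by 2.62 ± 0.058, NFATC1 fell by 2.60 and the adrenergic receptor ADRA2A fell by 2.43. OLMALINC and NFATC1 were well above background on 2 of 3 arrays with 5-aza-dC, and TIFA was at least 3.096-fold lower. Of 66 cell cycle and DNA replication genes 57 fell and 0 rose (adjusted p = 1.17e-11, and 0.0523 with an estimated correlation). CDC20 fell by 0.90 ± 0.0422, PRIM1 by 1.01 ± 0.0518 and POLA1 by 0.86 ± 0.048. Of 25 cholesterol biosynthesis genes 20 fell and 1 rose (adjusted p = 3.82e-08), with DHCR7 at -1.56, MVK at -1.25 and MSMO1 at -1.87. Of 40 MYCN targets and ribosome biogenesis genes 28 fell and 2 rose (adjusted p = 1.00e-04), with PRMT1 at -0.88 and PHB1 at -0.66. Of 30 integrated stress response genes 18 fell and 5 rose (adjusted p = 0.0078, and 0.22 with an estimated correlation), among them DDIT4, ASNS and SLC7A5.

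Several further lists were higher after 5-aza-dC than in DMSO. Of the genes reported as silenced by EZH2, 4 of 5 rose (adjusted p = 0.0078, and 0.0523 with an estimated correlation). CASZ1 rose by 1.43 ± 0.0572 and CLU by 0.86 ± 0.0889, and RUNX3 was at least 9.60-fold higher. NGFR changed by -0.07 (adjusted p = 0.616). Of 20 MHC class I genes 10 rose and 1 fell (adjusted p = 0.0078, and 0.0523 with an estimated correlation), including HLA-G at 1.16. Of 33 interferon-stimulated genes 17 rose and 4 fell (adjusted p = 0.00948, and 0.109 with an estimated correlation). MX2 was at least 4.40-fold higher, while IFI44 fell by 1.08. With median scaling the medians of these last 2 lists turned to -0.12 and -0.03, although both stayed above that of all genes. Of 30 imprinted genes 18 rose and 8 fell (adjusted p = 0.0031, and 0.115 with an estimated correlation), including MEST at 1.69 and INPP5F at 2.18.

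Markers of other cell types also moved with 5-aza-dC. Of 13 tested blood and endothelial markers 8 rose and 0 fell (adjusted p = 0.0078, and 0.0523 with an estimated correlation), and CLDN5 was at least 7.62-fold higher. Of 15 epithelial markers 8 rose and 2 fell (adjusted p = 0.012, and 0.0523 with an estimated correlation). Of 9 Schwann cell markers 5 rose and 1 fell (adjusted p = 0.0433, and 0.236 with an estimated correlation). These 3 calls did not hold under every scaling: the blood list was lost with normexp and with only probes well above background on all arrays, the epithelial list with spike-in scaling, and the Schwann cell list with quantile, spike-in and normexp, on slide 1 alone and without some single arrays. Adjusted over the list alone, 6 Schwann cell markers, 9 epithelial markers and 32 protocadherins rose after 5-aza-dC. In the same way 58 cell cycle genes, 29 MYCN targets, 19 stress response genes and 21 cholesterol genes fell.

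The apoptosis initiator CASP8 was at least 2.03-fold higher after 5-aza-dC, and CDKN1A changed by 0.49 (adjusted p = 0.201). EZH2 changed by -0.62 ± 0.154 (adjusted p = 0.00643), a call lost with spike-in scaling. DNMT1 fell by 0.43 ± 0.0577. Among DNA methylation genes DNMT3B rose by 1.12 ± 0.0433 and UHRF1 fell by 0.84 ± 0.0846, with 6 of 16 higher and 5 lower. MYCN was at -0.14 ± 0.0526 (adjusted p = 0.0436), but at 0.24 with quantile normalization and 0.11 with spike-in scaling, so its direction depended on the scaling. Other lists were not called for 5-aza-dC against DMSO. Of 21 HOX genes 5 rose and 1 fell, of 70 developmental transcription factors 25 rose and 25 fell, and of 44 neuronal differentiation genes 20 rose and 10 fell (adjusted p = 0.0773). Of 34 p53 targets 10 rose and 11 fell, including PLK2 at 2.03 and TP53INP1 at 1.36. Of 29 tumour suppressor genes often methylated in cancer 12 rose and 10 fell, and PYCARD and TNFRSF10D were at least 8.56-fold and 41.0-fold higher.

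Altogether 11768 genes differed between 5-aza-dC and DMSO, 5552 higher and 6216 lower, and 3204 by at least 2-fold, 2571 of them higher. Median scaling moves all log2 changes down, which leaves fewer 2-fold increases and more 2-fold decreases, so this balance depends on the scaling. Groups did not overlap for 66.9% of genes, against 10% by chance. Of the changed genes 47.2% were higher, but 19.4% with median and 74.9% with spike-in scaling. Within near-identical families, such as the MAGEA, CTAG1, HLA and protocadherin genes, a probe can bind transcripts of several members.

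**Figure D2:**
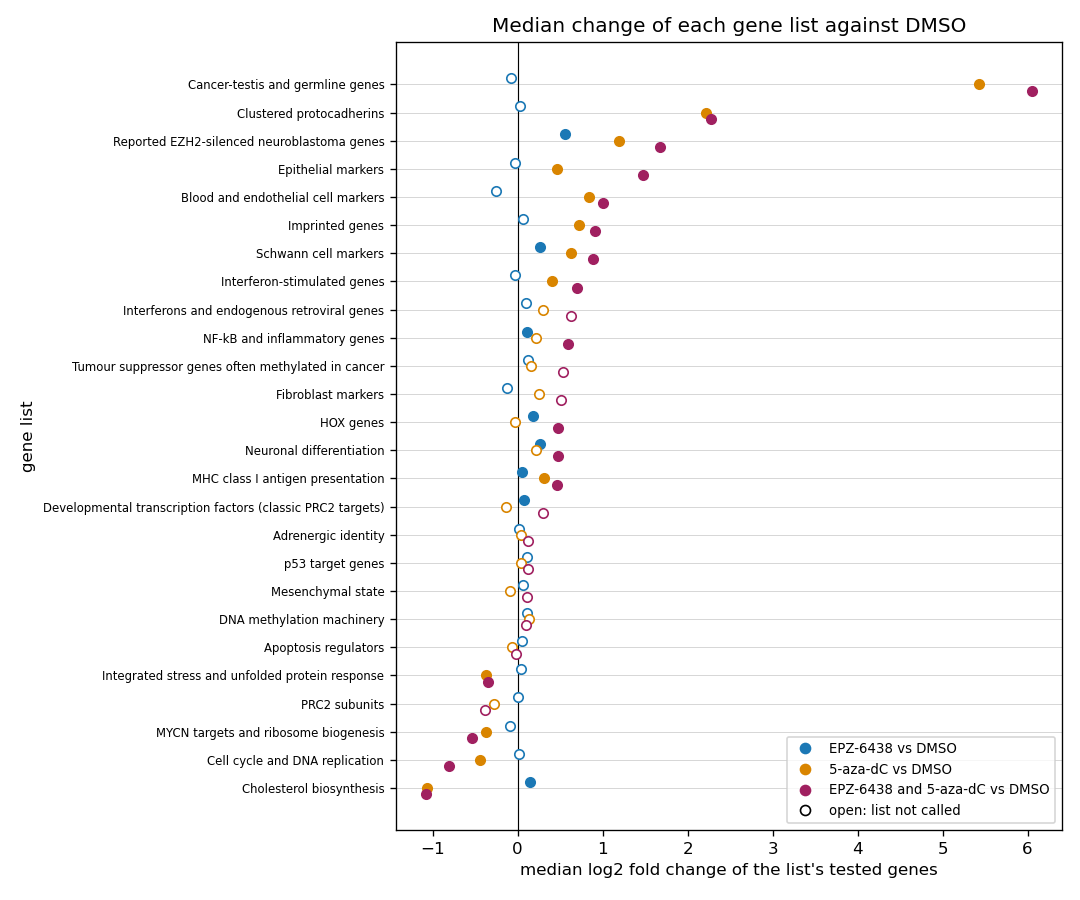
Median log2 fold change of the tested genes of each of the 26 lists (vertical axis) against DMSO, for EPZ-6438, 5-aza-dC and both drugs, filled where camera called the list. The cancer-testis list lies at 5.42 and 6.05 with 5-aza-dC and both drugs and the cholesterol list at -1.07 and -1.08; several smaller medians change sign with median scaling, as the HOX list does (-0.17 with both drugs).

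Both drugs together gave the widest change from DMSO. The germline genes RHOXF2, CTAG1A, TKTL1 and DMRTB1 were at least 1567-fold, 1165-fold, 2633-fold and 392-fold higher. EZHIP, which encodes an inhibitory partner of EZH2, was at least 353-fold higher (adjusted p = 8.37e-12). VEGFD fell by 4.07 ± 0.0766 on the log2 scale and the growth factor binding protein gene IGFBP5 fell by 3.05 ± 0.0524. ADRA2A fell by 2.93, OLMALINC fell by 2.91, NDNF fell by 2.69 and LRIG3, well above background on 2 of 3 arrays with both drugs, fell by 2.68. Of 66 cell cycle genes 65 fell and 0 rose (adjusted p = 4.14e-17), with a median of -0.80. CDK2 fell by 1.59 ± 0.057 and PRIM1 fell by 1.51 ± 0.0518. All 5 genes reported as silenced by EZH2 rose (adjusted p = 0.00123), among them CLU by 1.67 ± 0.0889, CASZ1 by 1.75 ± 0.0572 and NGFR by 1.05 ± 0.116, with RUNX3 at least 15.6-fold higher.

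Among cancer-testis genes 67 of 82 were higher than in DMSO and 6 lower (adjusted p = 5.13e-21), and of 34 protocadherins 31 were higher (adjusted p = 1.31e-10). Imprinted genes were higher in 22 of 30 and lower in 4 (adjusted p = 6.32e-05), epithelial markers in 11 of 15 (adjusted p = 0.00123), and blood and endothelial markers in 9 of 13 (adjusted p = 0.00481). The blood and endothelial call was lost after normexp and with only probes well above background on all arrays. Interferon-stimulated genes were higher in 23 of 33 and lower in 6 (adjusted p = 0.00152), with MX2 at least 23.2-fold higher. For the next 4 lists the medians turned negative with median scaling, at -0.17, -0.18, -0.17 and -0.04, while staying above that of all genes. They were HOX genes, 12 of 21 higher (adjusted p = 0.00538), MHC class I genes, 11 of 20 higher (adjusted p = 0.00538), neuronal genes, 27 of 44 higher and 8 lower (adjusted p = 0.00285, and 0.109 with an estimated correlation), and NF-kB genes, 11 of 17 higher and 4 lower (adjusted p = 0.0225, and 0.112 with an estimated correlation). NF-kB genes were not called with quantile normalization, normexp or flooring, or with only probes well above background on all arrays. NPY, a neuropeptide, was at least 174-fold higher and the neurofilament gene NEFH rose by 5.37 ± 0.134. Of 9 Schwann cell markers 8 were higher (adjusted p = 0.00197, and 0.0744 with an estimated correlation), a call lost after normexp.

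Genes of MYCN targets and ribosome biogenesis were lower in 31 of 40 cases (adjusted p = 1.47e-06) and cholesterol genes in 21 of 25 (adjusted p = 1.05e-06). Stress response genes were lower in 19 of 30 (adjusted p = 0.0124, and 0.211 with an estimated correlation), a call lost with quantile normalization and with only probes well above background on all arrays. MYCN itself was at -0.38 ± 0.0526 (adjusted p = 0.000123), but at 0.11 with quantile normalization. Adjusted over the list alone, 28 neuronal genes and 32 protocadherins were higher and 5 imprinted genes lower. In all 13132 genes differed, 6246 higher and 6886 lower, and 4213 by at least 2-fold, 3315 of them higher. With median scaling 8497 genes changed at least 2-fold, most of them lower, so the direction of the 2-fold changes depended on the scaling. Of the changed genes 47.6% were higher, but 18.9% with median scaling, 73.3% with spike-in scaling and 37.0% after normexp. Groups did not overlap for 71.1% of genes, against 10% by chance.

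Adding EPZ-6438 to 5-aza-dC raised developmental regulators and lowered cell cycle genes relative to 5-aza-dC alone. Of 21 HOX genes 13 rose and 0 fell (adjusted p = 2.06e-06). HOXD10 rose by 1.21 ± 0.0907 on the log2 scale and HOXD1 by 0.64 ± 0.0665. Of 70 developmental transcription factors 30 rose and 3 fell (adjusted p = 2.06e-06), with LHX1 at 1.29 ± 0.0502 and MSX1 at 1.18 ± 0.0551. Neither of these lists was called for the interaction (camera adjusted p = 0.109 and 0.213 with slide as a block). For both drugs against DMSO, 33 developmental transcription factors rose and 17 fell, and that list was not called (camera adjusted p = 0.0728). Of 66 cell cycle genes 51 fell and 0 rose (adjusted p = 5.87e-22). CDK2 fell by 0.85 ± 0.057, the replicative helicase gene MCM4 by 0.59 ± 0.0488 and POLE2 by 0.61 ± 0.0551. Several of the genes that rose were not well above background with 5-aza-dC alone. CRYM, KLK8 and DNAH3 were at least 6.20-fold, 3.35-fold and 3.11-fold higher, CTSZ and PRAMEF4 at least 2.86-fold and 2.44-fold. The antiviral gene MX1 was at least 2.09-fold higher. Decreases included CD86 (-1.96), CASC15 (-1.61), GOLGA6L4 (-1.40), IGFBP5 (-1.33), PLSCR5 (-1.30) and HNMT (-1.26), of which CD86 and GOLGA6L4 were not called under several alternatives.

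Of the 5 genes reported as silenced by EZH2, 4 rose on adding EPZ-6438 to 5-aza-dC (adjusted p = 0.00931, and 0.0663 with an estimated correlation). NGFR rose by 1.13 ± 0.116, CLU by 0.81 ± 0.0889 and CASZ1 by 0.33 ± 0.0572. RUNX3 was at 0.70 (adjusted p = 0.0485), a call lost when any 1 of the 6 arrays compared was left out. Cancer-testis genes were higher in 27 of 82 and lower in 5 (adjusted p = 0.00075). Their median was 0.14, and -0.07 with median scaling. Interferon-stimulated genes were higher in 14 of 33 and lower in 4 (adjusted p = 0.00374, and 0.07 with an estimated correlation), with CXCL11 at least 3.68-fold higher and MX2 at 2.40 ± 0.0957. Neuronal genes were higher in 16 of 44 and lower in 2 (adjusted p = 0.000122, and 0.07 with an estimated correlation). Epithelial markers were higher in 6 of 15 (adjusted p = 0.00177). MYCN targets were lower in 12 of 40 and higher in 1 (adjusted p = 0.000194). Imprinted genes were higher in 13 of 30 and lower in 3 (adjusted p = 0.00075, and 0.0803 with an estimated correlation), with a median of 0.19, and -0.02 with median scaling. The same scaling turned the blood and endothelial median from 0.21 to -0.01, with 5 of 13 higher (adjusted p = 0.0197, and 0.07 with an estimated correlation). Of 17 NF-kB genes 7 rose (adjusted p = 0.011, and 0.09 with an estimated correlation) and of 9 Schwann cell markers 3 rose (adjusted p = 0.0226, and 0.169 with an estimated correlation). These last 3 lists were not called after normexp correction, and the blood and endothelial list not with quantile normalization either. With only probes well above background on all arrays, these 3 lists and the cancer-testis and interferon lists lost their calls. Flooring ended the NF-kB and Schwann cell calls. Adjusted over the list alone, 32 developmental transcription factors, 29 cancer-testis, 15 interferon-stimulated, 17 neuronal and 8 NF-kB genes and 4 Schwann cell markers were higher. Lower by that adjustment were 54 cell cycle genes, 16 MYCN targets and 6 cancer-testis genes.

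In all 4855 genes differed between both drugs and 5-aza-dC, 2690 higher and 2165 lower, and 860 by at least 2-fold, 815 of them higher. Of the changed genes 55.4% were higher, but 19% with median and 69.1% with spike-in scaling. Groups did not overlap for 45.9% of genes, against 10% by chance. The count was 2283 on slide 1 alone and 7365 with median scaling.

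Against EPZ-6438 alone, both drugs together raised germline genes and protocadherins and lowered cell cycle, cholesterol and MYCN target genes. TKTL1, RHOXF2 and CTAG1A were at least 2827-fold, 1648-fold and 1225-fold higher, and MAGEA2B and DMRTB1 at least 586.9-fold and 412.6-fold. VEGFD fell by 4.15 ± 0.0766 on the log2 scale, with OLMALINC at -3.197 ± 0.23, IGFBP5 at -2.925 ± 0.0524, SCRG1 at -2.743 ± 0.0843 and ADRA2A at -2.652 ± 0.18, and BMP3 was at least 3.326-fold lower. Of 82 cancer-testis genes 68 rose and 8 fell (adjusted p = 4.25e-21), and of 34 protocadherins 29 rose and 0 fell (adjusted p = 1.48e-09). Of 66 cell cycle genes 65 fell and 0 rose (adjusted p = 1.03e-18), with CDK2 at -1.496 ± 0.057 and PRIM1 at -1.547 ± 0.0518. Of 25 cholesterol genes 22 fell and 1 rose (adjusted p = 1.16e-08), with HSD17B7 at -2.095 ± 0.0675, and of 40 MYCN targets 32 fell and 1 rose (adjusted p = 9.41e-06). The median of the MYCN target list was -0.42. Spike-in scaling moves every change of this comparison up by nearly that much, so the size of this fall depended on the scaling. Epithelial markers rose in 10 of 15 and fell in 1 (adjusted p = 0.00103), and blood and endothelial markers rose in 9 of 13 (adjusted p = 0.000954), with SPINT2 at 3.077 ± 0.0917 and CLDN5 at least 14.03-fold higher. The blood and endothelial call was lost with only probes well above background on all arrays.

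Of the 5 genes reported as silenced by EZH2, 4 were higher with both drugs than with EPZ-6438 alone and 0 lower (adjusted p = 0.00932, and 0.0577 with an estimated correlation). CASZ1 rose by 1.35 ± 0.0572, CLU by 1.45 ± 0.0889 and RUNX3 by 3.69 ± 0.224, and NGFR was at 0.18 (adjusted p = 0.21). Interferon-stimulated genes were higher in 21 of 33 and lower in 5 (adjusted p = 0.00163, and 0.0577 with an estimated correlation), with MX2 at least 24.38-fold higher. Imprinted genes were higher in 21 of 30 and lower in 4 (adjusted p = 0.000289, and 0.0662 with an estimated correlation), with NDN at least 7.268-fold higher. MHC class I genes were higher in 10 of 20 (adjusted p = 0.0301, and 0.0929 with an estimated correlation), and Schwann cell markers in 6 of 9 (adjusted p = 0.0301, and 0.203 with an estimated correlation). With median scaling the medians of these last 4 lists turned to -0.138, -0.192, -0.259 and -0.334. That scaling ended the MHC class I call, as did averaging probes or slide 1 alone, and the Schwann cell call, which quantile normalization, spike-in scaling, normexp and flooring ended too. Stress response genes were lower in 19 of 30 and higher in 5 (adjusted p = 0.00544, and 0.203 with an estimated correlation). Adjusted over the list alone, 7 Schwann cell markers and 22 imprinted genes were higher and 20 stress response genes lower. EZH2 was at -0.6454 ± 0.154 (adjusted p = 0.00433), and MYCN at -0.19 (adjusted p = 0.0104), but at 0.19 with quantile normalization and 0.20 with spike-in scaling. In all 12897 genes differed, 6289 higher and 6608 lower, and 3923 by at least 2-fold. Of the changed genes 48.8% were higher, but 16.8% with median and 80.9% with spike-in scaling, and groups did not overlap for 68.6% of genes, against 10% by chance.

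**Figure D3:**
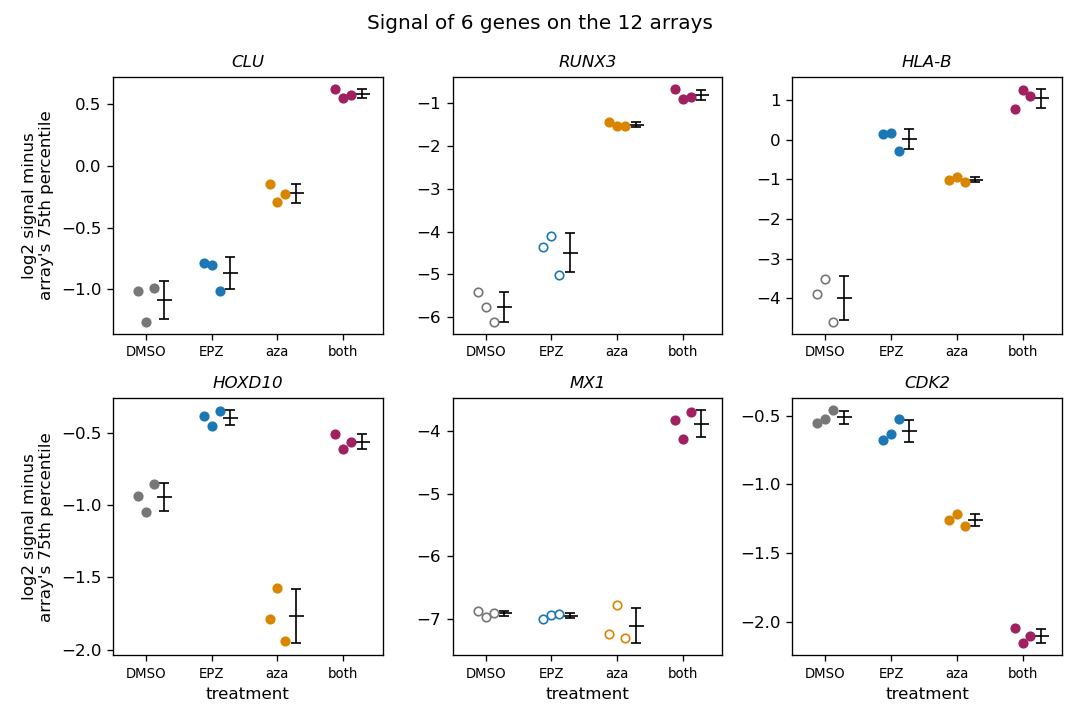
Log2 signal minus each array's 75th percentile (vertical axes, each with its own range) for 6 genes in the 4 treatments, with 1 point per array, and the mean and SD of 3 arrays as a bar beside them. Open points mark groups in which fewer than 3 arrays were well above background, as for MX1 in all groups except both drugs.

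EPZ-6438 lowered cell cycle genes in cells given 5-aza-dC, and the interaction term tested whether its effect differed from that without 5-aza-dC. In the cell cycle list the interaction was negative for 37 of 66 genes and positive for 0 (adjusted p = 2.28e-20). EPZ-6438 changed this list by a median of 0.02 without 5-aza-dC and -0.35 with it, an interaction median of -0.38. CDK2, POLE2 and MCM4 had interactions of -0.75 ± 0.0805, -0.68 ± 0.0779 and -0.60 ± 0.0689. In the cholesterol list 6 of 25 interactions were negative and 0 positive (adjusted p = 0.00119), including IDI1 at -0.53 ± 0.0871. EPZ-6438 changed this list by a median of 0.15 without 5-aza-dC and 0.01 with it. On top of 5-aza-dC 1 of its genes rose and 7 fell, and the list was not called (camera adjusted p = 0.42). The cell cycle and cholesterol interactions kept their calls with an estimated correlation (both adjusted p = 0.0376). Interferon-stimulated genes had 10 of 33 positive and 5 negative interactions (adjusted p = 0.0178, and 0.171 with an estimated correlation). MX1 and CXCL11 were well above background only with both drugs and MX2 only in the 2 groups with 5-aza-dC. Their interactions were called positive, also with values raised to the lowest signal well above background. That raise erases any change below this level, so neither the size nor the direction of the interactions was measured. Cancer-testis genes had 18 of 82 positive and 4 negative interactions (adjusted p = 0.00506, and 0.0855 with an estimated correlation). Blood and endothelial markers had 3 of 13 positive and 1 negative (adjusted p = 0.0177, and 0.0855 with an estimated correlation), and epithelial markers 2 of 15 positive (adjusted p = 0.0244, and 0.0949 with an estimated correlation). Of these 4 lists with positive interactions only the cancer-testis list kept its call with spike-in scaling, and with quantile normalization the blood and epithelial calls were lost, the epithelial call also on slide 1 alone and with array quality weights. With only probes well above background on all arrays the interferon and blood calls were lost, and the cancer-testis median turned to -0.138 relative to all genes (adjusted p = 0.482). Adjusted over the list alone, interactions were negative for 47 cell cycle and 8 cholesterol genes, and positive and negative for 25 and 7 cancer-testis genes, 13 and 5 interferon-stimulated genes and 5 and 1 blood and endothelial markers.

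**Figure D4:**
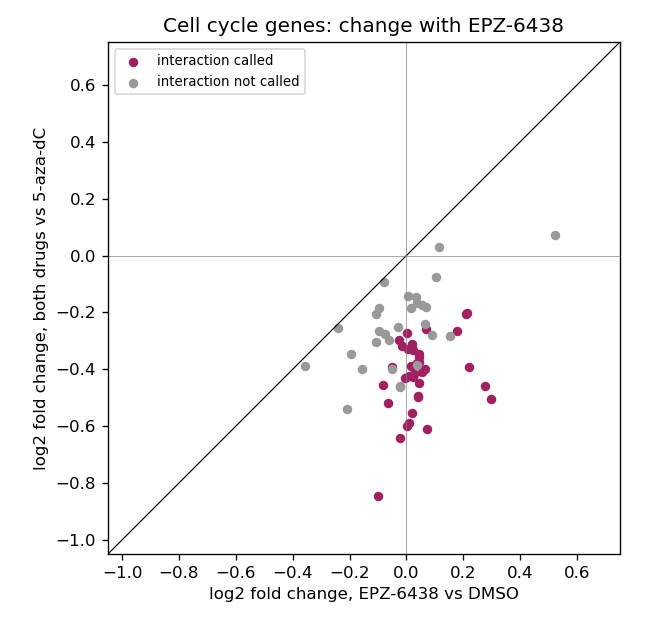
Log2 fold change of the 66 cell cycle genes with EPZ-6438 in the absence (horizontal axis) and presence (vertical axis) of 5-aza-dC, 1 point per gene, coloured by whether the interaction was called. The line marks equal effects, and with scaling to the 75th percentile all 66 genes lie below it. Spike-in scaling moves every point up relative to the line, so those nearest it, such as MKI67 and PCNA, would cross it.

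Some genes raised by each drug alone rose less with both drugs than the sum of the 2 single log2 changes, 114 of them with a called interaction of -1 or below. DYRK4 had an interaction of -2.497 ± 0.0894. HLA-DPB1, BEX5, F11R and YBX3 were not well above background in DMSO, and with DMSO at the lowest signal well above background their interactions were -1.52, -2.21, -1.65 and -1.72, as upper bounds. CD33 was also called, with signals well above background on 0 DMSO and 1 5-aza-dC arrays, a call lost without single arrays of every group. HLA-B, HLA-C and TAP2 had interactions of -1.95, -1.49 and -1.01. The list of genes reported as silenced by EZH2 was not called (adjusted p = 0.725), with 1 of 5 interactions positive and 1 negative. The positive one was CLU, not called for EPZ-6438 alone, at 0.58 ± 0.126 (adjusted p = 0.0159), which was not called on slide 1 alone. CTSZ, DNAH3, HOXB2, PRAMEF4 and TNFSF9 were well above background only with both drugs, and SH2D4B otherwise on 1 DMSO array. Their interactions were called positive but have no measured size, and the dim signals leave their direction undecided. Against 5-aza-dC alone HOXB2, TNFSF9 and SH2D4B were at least 6.717-fold, 4.053-fold and 3.51-fold higher. For 244 genes the signal was well above background on all 3 arrays with both drugs and on none of the 9 others. The interaction was called positive for 148 of them, which rests on those dim signals. A further 973 genes were off without 5-aza-dC and on in both groups with it. In all 2574 genes had an interaction, 1215 positive and 1359 negative, or 47.2% positive, but 13.0% with median and 79.9% with spike-in scaling. The count was 1143 with no filter on dim probes, 478 on slide 1 alone, and 1212 without the 3 arrays whose gene spot variation was out of range.

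Genes changed by the 2 drugs overlapped. Of the genes higher with EPZ-6438 against DMSO, 982 were also higher with 5-aza-dC, where independent lists would share 464.7, and 332 were lower with both, where they would share 295.1. With median scaling 186 were lower with both, fewer than the 217.4 of independent lists. A further 353 genes were higher with EPZ-6438 and lower with 5-aza-dC, and 311 the reverse. Both comparisons use the same DMSO arrays. In simulations without any change, where simulated DMSO arrays were shared in the same way, no calls were shared (0 in 20 simulations). Groups without changes yield few calls to share, so this sets no standard for the overlap. The simulations had r = 0.507 across genes, against 0.174 observed. The covariance was 0.0953 against 0.0304 simulated, a difference of 0.0649. The 3 DMSO arrays are too few to split, so part of the excess overlap can come from them. EPZ-6438 against DMSO and both drugs against 5-aza-dC share no arrays. There 942 genes were higher in both, where independent lists would share 225.1, and 253 lower in both, against 102.8 (r = 0.316 across genes). A further 86 were higher in the first and lower in the second, and 75 the reverse. All 4 groups share 1 estimate of each gene's spread, so genes with a small spread are called more readily in every comparison. Independent lists can thus set too low a standard for both overlaps.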

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

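The tests of array scaling, of signals at the array floor and of cells of other types were chosen after the results were seen, and the other tests before the data were examined. The results below stand out because the effect of EPZ-6438 differed between cells with and without 5-aza-dC, by the interaction term. It did so for 2574 genes. Of 100 drawn assignments of the 12 arrays to 4 groups of 3, 2 gave as many genes as the real one, which is 1 of them (real value 2578 over genes with values on all 12 arrays, highest other 4735). The draws put arrays with and without 5-aza-dC into 1 group, which raises the spread within groups and holds counts down, so they do not decide whether chance gives as many. That other draw put 5 of the 6 arrays with 5-aza-dC on one side of the contrast, but 10 further draws did so and called 0 genes, so the cause of its count is open.

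Cell cycle genes were lower when EPZ-6438 was added to 5-aza-dC than without it, with a median interaction of -0.384 over 66 genes. Against a distortion that depends on brightness, the list lay at percentile 0 of 10000 lists matched on brightness, whose lowest median was -0.191. Against the scaling of the arrays, the list's own median interaction was below 0 and called under 5 of 5 scalings (-0.252 to -0.642), although 3 of them differ by 1 constant per array and cannot turn its place relative to other genes. A biological hypothesis is that cells given both drugs divided less than with either drug alone. Falls in CDK2, MCM4 and POLE2 would go with it, but these 3 were named for their small p-values. With 5-aza-dC, the fitted change with EPZ-6438 was below 0 for 64 of 66 genes. CCNE1 and CCNE2 were at 0.073 and 0.030. MKI67 changed by -0.080 without and -0.094 with 5-aza-dC, and PCNA by -0.240 and -0.254, with no interaction called for either. Cell number, cell death and division were not measured, and an altered share of dying cells stays open.

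Interactions opposite to both single effects were called at -1 or below for 114 genes raised by each drug alone, including BEX5 (-3.747 as fitted and -2.21 with values raised to the floor), F11R (-3.704 and -1.65), HLA-DPB1 (-3.614 and -1.52) and YBX3 (-2.638 and -1.72), whose second values are upper bounds. Signals at the array floor in DMSO were weighed as the cause, since 47 of these genes were not well above background on any DMSO array. With values raised to the floor, 76.3% kept their call and direction, and the median interaction went from -1.44 to -1.15. That lies between the bounds set for the test, so the floor and a shared ceiling of both drugs cannot be told apart for the remainder. Interactions in the direction of the combination were called for 460 genes higher by at least 2-fold. With values raised in the same way 89.1% kept their call, and their median went from 1.67 to 1.19. This does not decide on the floor in the other groups as the cause. For 329 of them DMSO was below background on all 3 arrays, where raising DMSO moves the interaction up. For 147 all 3 other groups were below background, so the raised values leave only the excess of the combination over the floor. These 147 have no measured size.

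After 5-aza-dC 8 of 13 blood and endothelial markers rose, and of 15 epithelial markers 8 rose and 2 fell (adjusted p = 0.0078 and 0.012, and 0.0523 for both with an estimated correlation), and the lists had median interactions of 0.6093 (blood and endothelial, adjusted p = 0.0177, and 0.0855 with an estimated correlation) and 0.3869 (epithelial, adjusted p = 0.0244, and 0.0949 with an estimated correlation). Cells of other types in the culture would bring all their abundant transcripts. Of 45 list members on the array, 53.3% were higher after 5-aza-dC or well above background in DMSO, which decides nothing. A second test was added after the first came out undecided: 4 of 7 lineage markers (HBB, CD3E, CDH1 and KRT5) were not well above background on any of the 12 arrays, and PECAM1, MS4A1 and KRT14 were well above it on 1 array each, which by the bound set for this test left cells of other types open as well. Release of such genes from DNA methylation in the neuroblastoma cells is the biological alternative, and DNA methylation was not measured.

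The cancer-testis list had a median interaction of 0.2363 (adjusted p = 0.00506, and 0.0855 with an estimated correlation), which was -0.0213 with median scaling and, relative to all genes, -0.138 with only probes well above background on all arrays (adjusted p = 0.482). The interferon-stimulated list had 0.1371 (adjusted p = 0.0178, and 0.171 with an estimated correlation), which was -0.121 with median scaling and not called with spike-in scaling, and the cholesterol list had -0.2791. The fit gave interactions to SH2D4B (4.561), CTSZ (4.305), DNAH3 (4.066), HOXB2 (3.599), PRAMEF4 (3.585), TNFSF9 (3.523) and CD33 (-2.88), which rest on signals not well above background and give neither a size nor an order. DYRK4, well above background on all 12 arrays, had -2.497. Of the genes reported as silenced by EZH2, CLU had a positive interaction (0.5847) and 1 other a negative one, and the list was not called (adjusted p = 0.725).

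For the 5 comparisons of 2 groups, 6 arrays make only 10 splits into 3 and 3, which are too few for a share under 0.05. Every split except the real one also mixes the 2 treatments within a group, which raises the spread and holds its count down. In each comparison 1 of 10 splits, the real one, gave as many genes. For EPZ-6438 against DMSO the real split called 1496 genes and the highest other 1, and for both drugs against 5-aza-dC 4969 and 1. For 5-aza-dC against DMSO it called 11630, for both drugs against DMSO 13114 and for both drugs against EPZ-6438 12569, each with 0 as the highest other.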

How the results depend on the processing

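Normexp, spike-in scaling, flooring, slide 1 alone and leaving out 3 arrays were chosen after seeing the data; the other settings were set before. Of 445 gene and list counts, 405 stayed within 1.5 times their value. Of 4024 list results 3810 stayed as called or not called, 92 lost the call, 121 gained it and 1 reversed. Of 12886 results for reported genes 12243 stayed so, 549 lost the call, 77 gained it and 17 reversed. Direction was compared only for results called in the main fit. Sign changes of results not called there are therefore not among the reversals. Where not stated, the cause was not tested.

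With normexp, which compresses low signals through its offset, genes changed at least 2-fold numbered 86 (EPZ-6438), 1036 (5-aza-dC), 1546 (both against DMSO), 147 (both against 5-aza-dC), 1424 (both against EPZ-6438) and 115 (interaction). MBD2 reversed for EPZ-6438 (-0.12), EGR2 for both against 5-aza-dC (-0.00581), and VWF (0.215) and ICAM1 (-0.0163) for the interaction. Planned normexp on mean signals was not run, since the files lack them.

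With quantile normalization MYCN reversed for 5-aza-dC (0.242) and for both drugs against DMSO (0.107) and EPZ-6438 (0.187). With spike-in scaling it was 0.11 for 5-aza-dC and 0.195 for both against EPZ-6438, and 3 lists were called for the interaction. With median scaling 1699 genes changed with EPZ-6438, 7365 for both against 5-aza-dC and 3870 for the interaction. At least 2-fold changes numbered 8497 for both against DMSO and 8304 against EPZ-6438, and 582 genes were higher with each single drug. Reversed were TET1 for both against 5-aza-dC (-0.00944), and PMP22 (-0.334) for both against EPZ-6438.

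With no filter on dim probes 1545 genes changed with EPZ-6438 and 1143 by interaction, and 11 lists were called for the interaction. IRX2 was -1.58 for both against 5-aza-dC and -1.52 for the interaction, and MBP -0.441 for both against EPZ-6438. With only probes well above background on all 12 arrays, fewer genes were tested, and at least 2-fold changes numbered 200 (EPZ-6438), 1246 (5-aza-dC), 1843 (both against DMSO), 225 (both against 5-aza-dC), 1601 (both against EPZ-6438) and 153 (interaction). There 8 lists were called for both against 5-aza-dC and 3 for the interaction, and the cancer-testis interaction was -0.138. With values floored 321 genes changed at least 2-fold with EPZ-6438, and VWF was -0.0307 for EPZ-6438 and 0.86 for the interaction. CCL2 was at -0.184 for 5-aza-dC, but was not well above background on any array of the 2 groups compared. That value is a difference between array floors and not a change of CCL2.

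With fewer arrays, slide 1 alone called 1053 genes for EPZ-6438, 2283 for both against 5-aza-dC and 478 for the interaction, 289 of at least 2-fold. Without the 3 arrays of out-of-range gene spot variation the interaction had 1212 and 388. Only the arrays compared gave 1496 genes for EPZ-6438. Leaving out single arrays gave 2029 to 2327 genes for EPZ-6438 and 1817 to 2384 for the interaction. Camera with an estimated correlation called 4 lists for 5-aza-dC, 6 for both against 5-aza-dC, 7 against EPZ-6438 and 2 for the interaction. Fry called 17 for EPZ-6438, 22 for 5-aza-dC, 23 for both against EPZ-6438 and 18 for the interaction.

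With the replicate block the 6 comparisons called 2709, 11880, 13219, 4793, 12956 and 2433 genes (EPZ-6438, 5-aza-dC, both against DMSO, both against 5-aza-dC, both against EPZ-6438, interaction). Residuals of arrays with the same replicate number had r from -0.0754 to 0.197 across genes (18 pairs, median 0.0318). Those with different numbers had r from -0.238 to 0.167 (36 pairs, median -0.0164), so the ranges overlapped. Each group has few arrays and the replicate number partly coincides with the slide, so this does not decide whether the numbers pair arrays. Dim signals limit the folds of genes not well above background in 1 group.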

Other observations

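The detection calls gave a pattern outside the planned comparisons. Of 20707 genes, 244 were well above background on all 3 arrays with both drugs and on no other array, 170 of them with a symbol. Of the 244, 43 did not differ from 5-aza-dC alone by the fit. Arrays with both drugs had more spots well above background overall than those with 5-aza-dC alone (57.9% against 54.9%), and the number of such genes was not tested. Further, 14 were so only with EPZ-6438 and 1 only with 5-aza-dC, and 973 were so in both groups with 5-aza-dC and in neither group without it. HOXB2 had the largest bound of the first set among genes with a symbol. It was at least 6.717-fold higher with both drugs than with 5-aza-dC alone, and was picked out after its values were seen.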
